A study of Mus musculus with 10 samples.

How the data were processed

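RNA was measured in sorted splenic naive CD4 T cells of C57BL/6 mice in 10 libraries of 4 groups, given by the treatment and stimulation in the labels: vehicle unstimulated (3 libraries), Compound 10 unstimulated (2), vehicle stimulated (2) and Compound 10 stimulated (3). Per the labels' protocols, total RNA was made into libraries with a Clontech SMART-seq kit, which does not mark the strand, so reads from a gene and an overlapping antisense gene cannot be told apart. The submitters' processing notes name cutadapt, kallisto and the mouse build mm10, and their versions and the transcript annotation are not given in the sources used here. The estimated counts were made by the authors with kallisto, which shares reads among compatible transcripts, and were deposited as 1 table per library with 1 row per transcript, per the file headers. The same deposited tables hold TPM values and the length and effective length of each transcript, per the file headers. TPM values were not tested. The effective lengths were identical in every library.

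Transcripts were matched to genes of GENCODE release M21 (mm10) by their Ensembl identifier without its version, which matched 108214 of 109617 transcripts. The 1403 unmatched transcripts held 0.507% to 0.671% of the counts of a library and were left out. Estimated counts were summed per gene and rounded to whole numbers, as the count model requires. Because kallisto divides reads among similar sequences, values of genes with close paralogs or pseudogenes, such as Hspa1a and Hspa1b, are uncertain. Coordinates are those of this annotation, counted from 1.

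Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. All 10 libraries entered a single fit with 1 coefficient per group, so that the 4 groups shared the estimate of spread, with TMM scaling factors (0.731 to 0.850 in stimulated and 1.20 to 1.34 in unstimulated libraries) and the filterByExpr filter by group, which left 14417 of 45321 genes. Each contrast was tested with edgeR's quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg. Genes with adjusted p under 0.05 are described as called, higher, lower, risen or fallen. The SE of a log2 fold change was taken from the estimate and its F statistic, which makes it too small where a group holds few counts and the change is large. Group levels are CPM with TMM factors, as mean ± SD over libraries. Where a group held 0 counts, the fold was computed against a floor of 3 counts over the group, and a ratio to a group with 1 to 3 counts is given with its 95% counting interval. The contrasts were stimulated against unstimulated cells under vehicle and with Compound 10, Compound 10 against vehicle in stimulated and in unstimulated cells, and the interaction. No replicate number is said to pair libraries, so no block was used.

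The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took a panel of 16 T cell activation genes in each comparison. It added the 5 largest rises and the 5 largest falls with adjusted p under 0.05, an average log2 CPM of at least 3 and no overlap between the groups' libraries (the last not for the interaction). It left out unnamed gene models, ribosomal protein, mitochondrial, immunoglobulin and T cell receptor segment genes. For each list it added up to 4 members with the smallest adjusted p. The 16 lists were cytokines and chemokines, AP-1 and bZIP factors, immediate-early and MAPK feedback genes, NFAT with anergy or exhaustion genes, NF-kB targets, activation surface and nutrient proteins, naive and quiescent genes, Myc targets with ribosome biogenesis, heat shock, integrated stress and unfolded protein response, NRF2 targets, aryl hydrocarbon receptor targets, p53 targets, cholesterol synthesis, interferon response, and glycolysis with hypoxia. Another 8 lists held markers of B cells, CD8 T cells, myeloid cells, NK cells, erythroid cells, regulatory T cells, memory or effector T cells and T cell identity. Lists were tested with camera in limma on voom values, with an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a kind. A list of fewer than 2 tested genes was not tested.

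A share of induced or repressed genes counted those with an absolute log2 fold change of at least 1 under vehicle, with Wilson 95% intervals, beside 20 simulations with no compound effect. All 8 pairs of libraries within groups differed by more than sampling noise (lowest chi-square per degree of freedom 13.7), so none was counted as a repeat. The test was checked on simulated counts of 14417 genes of which 200 were changed. It recovered 45%, 43%, 41%, 47% and 7% of 2-fold changes and 93%, 94%, 99%, 96% and 73% of 4-fold changes, for stimulation under vehicle, stimulation with Compound 10, Compound 10 in stimulated cells, Compound 10 in unstimulated cells and the interaction, in that order. Of the calls in these simulations 4.17%, 8.05%, 4.76%, 4.03% and 9.09% were unchanged genes, so that 2-fold differences in the interaction mostly lay beyond the reach of these libraries.

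The alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, limma-voom, no filter or a stricter filter (at least 5 CPM in at least 2 libraries), offsets for transcript length, leaving out the 20 most abundant genes, fitting only the groups compared, the replicate number or the run of sample index numbers as a block, stricter thresholds, other choices of induced genes, and leaving out each library. Leaving out the 3 libraries of the third index run, upper-quartile scaling and no scaling beyond library totals were chosen after seeing the data. The reference held transcripts but no genome sequence, so promoters were not analysed here. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.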

Results

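Gene expression was measured by RNA sequencing in naive CD4 T cells, the mature helper T cells that have not yet met antigen. The cells were sorted from the spleens of C57BL/6 mice as CD4+CD62L+CD69- cells. They were exposed for 1 h to 12.5 µM Compound 10 or to its solvent DMSO (vehicle). The series' own design text describes the compound as a chemical inhibitor of NFAT:AP-1, the complex of the calcium-regulated transcription factor NFAT with the Fos and Jun proteins of AP-1. The cells were then left unstimulated or were stimulated for 2 h with 10 nM PMA and 1 µM ionomycin. PMA is a phorbol ester that activates protein kinase C and ionomycin is a calcium ionophore, and the pair bypasses the T cell receptor. The groups were unstimulated vehicle (n = 3), unstimulated Compound 10 (n = 2), stimulated vehicle (n = 2) and stimulated Compound 10 (n = 3). The labels do not say that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

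The 10 libraries held between 10694591 and 33486259 estimated counts. The totals were 14382600, 16093611 and 27857586 in unstimulated vehicle cells and 12580160 and 33486259 in unstimulated Compound 10 cells. They were 10694591 and 14913786 in stimulated vehicle cells, and 11629270, 13822919 and 14017826 in stimulated Compound 10 cells. Genes of T cell identity (the CD3 chains, Cd4, Lck, Zap70 and others) summed to between 2302 and 3712 normalised counts (CPM, scaled to the library total) in each library. B cell markers summed to between 83.4 and 361 CPM and myeloid markers to between 73.3 and 203 CPM. Markers of regulatory T cells summed to between 98.5 and 226 CPM and those of memory or effector T cells to between 179 and 291 CPM. The memory or effector sum was higher in each Compound 10 library than in any vehicle library of the same state. It was at most 228 against at least 230 CPM in unstimulated cells, and at most 231 against at least 245 CPM in stimulated cells. By camera this list did not pass for Compound 10 in either state (adjusted p = 0.0970 and 0.681). NK cell markers (3.33 to 15.6 CPM), CD8 T cell markers (1.99 to 8.60 CPM) and erythroid markers (0.135 to 0.924 CPM) were near the floor. Gene models resembling ribosomal RNA took 3.70% to 6.12% of the counts in unstimulated and 6.43% to 12.2% in stimulated libraries, and the 20 most abundant genes took 13.3% to 15.6% and 20.9% to 26.8%. The first principal component held 61.1% of the variance and separated stimulated from unstimulated libraries. The second held 20.3% and separated Compound 10 from vehicle, and the third held 8.34%. Of 45321 genes, 14417 had enough counts to be tested.

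The first comparison asked what stimulation changed in vehicle-treated cells. Il2, the gene of the T cell growth factor interleukin-2 (chromosome 3, 37120523 to 37125959, mm10), went from 0.0616 ± 0.0425 CPM (SD, n = 3; 4 counts in all) to 363 ± 25.3 CPM (SD, n = 2), a log2 fold change of 12.54 ± 0.38 (SE). With only 4 counts in the unstimulated group this SE is too small. The chemokine gene Ccl4 rose by 9.18 ± 0.46 on the log2 scale, the endothelial lipase gene Lipg by 7.71 ± 0.89 and the zinc finger transcription factor gene Egr3 by 7.11 ± 0.33. The semaphorin gene Sema7a rose 128-fold. Among named genes with an average log2 CPM of at least 3 and no overlap between the groups' libraries, the largest falls were those of the protease gene Bace1 (-4.35 ± 0.39), Zkscan14 (-3.78 ± 0.22), Crebl2 (-3.76 ± 0.58), Txnl4b (-3.73 ± 0.36) and the ubiquitin ligase gene Fbxo32 (-3.39 ± 0.28). All 16 genes of a panel of T cell activation fixed in advance rose. Il3 and Csf2 had 0 counts in unstimulated vehicle cells and were at least 140-fold and at least 99.1-fold higher after stimulation, against a floor of 3 counts over the group. The cytokine genes Tnf and Ifng rose by 6.87 and 5.83, the CD40 ligand gene Cd40lg by 6.97, the receptor gene Il2ra by 5.14 and the early activation marker Cd69 by 3.80. The transcription factor genes Myc, Nr4a1, Egr2, Nfatc1, Egr1, Fos and Jun rose by 6.32, 5.57, 4.43, 3.70, 3.56, 3.20 and 1.60. The NF-kB inhibitor gene Nfkbia rose by 1.45. In all, 5617 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2814 higher and 2803 lower.

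Of the 16 gene lists fixed in advance, 12 rose with stimulation under vehicle by camera, a test of a list against the other genes. Among 24 tested cytokine and chemokine genes 21 rose and 2 fell (camera adjusted p = 1.13e-12), with Tnfsf11, the gene of RANK ligand, at 5.74 ± 0.22 and Fasl, the gene of a death receptor ligand, at 5.05 ± 0.20. Immediate-early and MAPK feedback genes had 27 of 30 higher and 2 lower (3.52e-18). T cell activation surface and nutrient proteins had 22 of 24 higher and 0 lower (1.03e-16). NF-kB targets had 20 of 27 higher and 3 lower (6.11e-10). These 4 pairs of counts were the same adjusted over the list alone. Myc targets and ribosome biogenesis genes had 26 of 30 higher and 0 lower (1.03e-14), among them Gnl3 at 2.64 ± 0.13 and Ppan at 2.81 ± 0.16, also 26 adjusted over the list alone. AP-1 and related factors had 13 of 18 higher and 0 lower (9.83e-09; 14 adjusted over the list alone), led by Fosl1 at 5.38 ± 0.23. These 6 lists also rose with an estimated correlation between genes, at adjusted p between 0.00487 and 0.0311. The other 6 did not, at adjusted p between 0.0644 and 0.136 with an estimated correlation. These were NFAT and exhaustion genes (13 higher, 3 lower of 26), glycolysis and hypoxia genes (17 and 3 of 27) and aryl hydrocarbon receptor targets (3 and 0 of 4), each with the same counts adjusted over the list alone. They also were heat shock genes (12 and 1 of 17; 13 and 1 adjusted over the list alone), the integrated stress and unfolded protein response (13 and 2 of 25; 13 and 2) and NRF2 targets (10 and 3 of 27; 10 and 4 over the list alone). Naive and quiescent genes had 8 higher and 10 lower of 30, p53 targets 8 and 7 of 23 (9 and 7 over the list alone), cholesterol synthesis genes 13 and 5 of 27, and interferon response genes 4 and 5 of 26. The other 3 had the same counts over the list alone, and none of the 4 passed camera (adjusted p between 0.0589 and 0.636). T cell identity markers rose together (7 of 10 higher, 0 lower; camera adjusted p = 0.00196, and adjusted p = 0.124 with an estimated correlation), led by Trac, a constant segment of the T cell receptor, at 2.37 ± 0.13.

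Levels after stimulation are relative to the scaling of the libraries. With no scaling beyond the library totals, the median gene lay at -0.83 in the stimulation effect under vehicle and the calls became 1202 higher and 6610 lower. Without the first stimulated vehicle library the count fell to 3606.

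**Figure D1:**
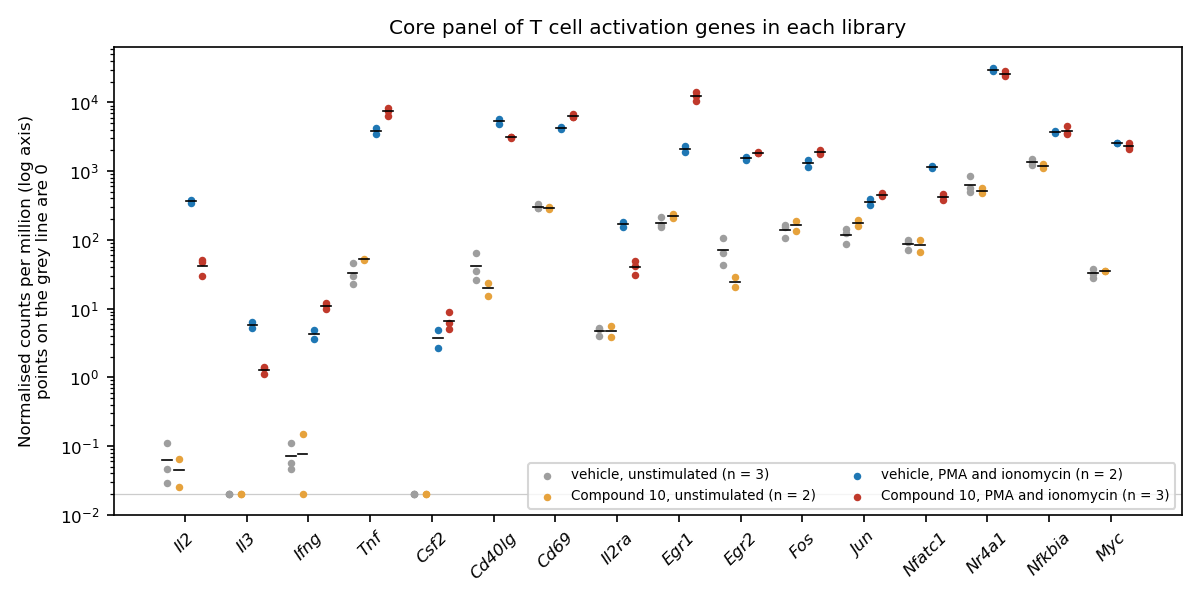
Level of each of the 16 panel genes in CPM on a logarithmic axis, with 1 point per library, a bar at the mean of each of the 4 groups and libraries at 0 drawn on the grey line. Il2 stood at 363 CPM in stimulated vehicle cells and 42.2 CPM in stimulated Compound 10 cells, while Egr1 stood at 2087 and 12284 CPM.

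In cells given Compound 10, stimulation still raised all 16 panel genes. Il2 rose by 9.94 ± 0.47 on the log2 scale, from 0.0445 ± 0.0274 CPM (SD, n = 2) to 42.2 ± 11.3 CPM (SD, n = 3). The unstimulated group held only 2 counts, so the SE is again too small. The ratio has a counting interval of 331 to 9911, which like the floors covers counting error only. Egr3 rose by 8.36 ± 0.42, Ccl4 by 8.09 ± 0.48, the adhesion receptor gene Slamf7 by 7.41 ± 0.73 and Cd40lg, the gene of the CD40 ligand through which helper T cells act on B cells, by 7.32 ± 0.44. Within the same limits of abundance and overlap, the largest falls were in Zfp874a (-3.80 ± 0.56), Pagr1a (-3.55 ± 0.97), the mitochondrial ribosomal protein gene Mrpl34 (-3.46 ± 0.30), Ppil1 (-3.23 ± 0.20) and Slfn1 (-3.20 ± 0.25). Pagr1a was no longer called without the second unstimulated Compound 10 library (-3.36, adjusted p = 0.0618 by edgeR's quasi-likelihood test) or the first stimulated one (-3.06, adjusted p = 0.0573). Other panel genes rose by 7.16 (Tnf), 6.68 (Ifng), 6.25 (Egr2), 6.03 (Myc), 5.79 (Egr1), 5.66 (Nr4a1), 4.45 (Cd69), 3.55 (Fos), 3.12 (Il2ra), 2.37 (Nfatc1), 1.69 (Nfkbia) and 1.36 (Jun). Il3 and Csf2 were at least 24.3-fold and at least 125-fold higher than in unstimulated cells, where both had 0 counts.

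Stimulation with the compound changed 3816 genes, 1844 higher and 1972 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted). Across the 14417 genes its effects correlated with those under vehicle (Pearson r = 0.617, Spearman rho = 0.628; genes are not independent replicates). Both effects were called for 2776 genes, with opposite signs for 58, while 2841 were called under vehicle alone and 1040 with the compound alone. A call in 1 condition alone is not a test of the difference, which the interaction gives. Again 12 lists rose by camera, and 5 of them also with an estimated correlation, at adjusted p between 0.00818 and 0.0138. Of these, cytokines had 18 of 24 higher and 2 lower (20 and 2 adjusted over the list alone), and immediate-early genes 25 and 1 of 30 (26 and 1). AP-1 factors had 12 and 1 of 18 (13 and 1), NF-kB targets 20 and 2 of 27 (21 and 2) and activation surface proteins 17 and 0 of 24 (18 and 0). Among Myc targets and ribosome biogenesis genes 10 of 30 were higher and 2 lower (12 and 2 adjusted over the list alone; camera adjusted p = 0.00015, and adjusted p = 0.0588 with an estimated correlation). The remaining 6 risen lists had adjusted p between 0.0775 and 0.309 with an estimated correlation. They were NFAT and exhaustion genes (14 and 1 of 26; 14 and 1), heat shock genes (10 and 0 of 17; 10 and 1) and the stress and unfolded protein response (8 and 1 of 25; 10 and 1). NRF2 targets (6 and 1 of 27; 6 and 1), cholesterol synthesis genes (7 and 4 of 27; 7 and 4) and glycolysis genes (11 and 4 of 27; 12 and 4) completed them. Naive genes (4 and 10 of 30; 4 and 10), p53 targets (4 and 2 of 23; 6 and 2), interferon genes (2 and 4 of 26; 2 and 2) and aryl hydrocarbon receptor targets (1 and 1 of 4; 1 and 1) did not pass (adjusted p between 0.11 and 0.965). Memory or effector markers (7 of 11 higher, 1 lower) and T cell identity markers (3 of 10 higher, 0 lower) each had camera adjusted p = 0.0216, and adjusted p = 0.17 and 0.176 with an estimated correlation. With no scaling the median gene lay at -0.60 and 810 genes were higher against 5219 lower. Without the second unstimulated Compound 10 library the count was 2398.

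**Figure D2:**
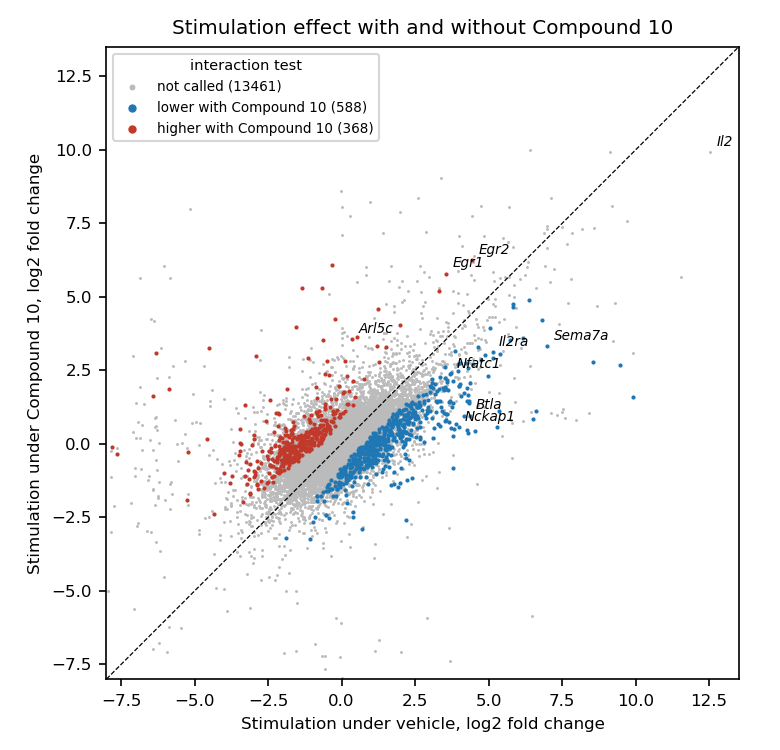
Stimulation effect (log2 fold change) under vehicle on the horizontal axis against the effect with Compound 10 on the vertical axis, 1 point per tested gene, with the diagonal of equal effects and the genes whose effects differed by the interaction test marked. The correlation across genes was 0.617, and 11 genes lie outside the axes.

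The comparison named by the series' design, Compound 10 against vehicle, was made first in stimulated cells. Il2 was 8.59-fold lower with the compound, at 42.2 ± 11.3 CPM (SD, n = 3) against 363 ± 25.3 CPM (SD, n = 2), a log2 fold change of -3.10 ± 0.23 (adjusted p = 4.17e-05, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Il2ra, which encodes the alpha chain of the interleukin-2 receptor, fell from 168 ± 22.6 to 40.3 ± 9.02 CPM (-2.06 ± 0.23). Nfatc1, the gene of an NFAT factor that is itself induced on activation, fell from 1143 ± 53.9 to 427 ± 39.2 CPM (-1.42 ± 0.19). The immediate-early gene Egr1 went the other way, from 2087 ± 293 to 12284 ± 1691 CPM (2.56 ± 0.21). Among genes within the limits of abundance and overlap given above, the largest rise was that of Arl5c, the gene of a small GTPase of the ARF family (30.02 ± 1.49 to 604 ± 59.7 CPM, 4.33 ± 0.19). Genes of the mitotic spindle and kinetochore followed, with Tpx2 at 3.58 ± 0.44, Cenpe at 3.33 ± 0.27 and Incenp at 3.11 ± 0.34, beside Sh3d21 at 3.57 ± 0.45. Within these limits the largest falls besides Il2 were in Nckap1, a regulator of actin polymerisation (71.2 ± 8.24 to 6.11 ± 2.70 CPM, -3.53 ± 0.35), Lipg (-2.93 ± 0.68), the nuclear import factor gene Kpna6 (-2.67 ± 0.25) and the helicase gene Dhx33 (-2.66 ± 0.26).

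Among the other cytokine genes of the panel, Tnf and Ifng rose while Il3 fell like Il2. Tnf went from 3874 ± 513 to 7445 ± 1024 CPM (0.94 ± 0.26, adjusted p = 0.0199, edgeR quasi-likelihood, Benjamini-Hochberg), Ifng rose by 1.38 ± 0.41 (0.0309) and the early activation marker Cd69 by 0.59 ± 0.13 (0.00734), while Il3 fell by 2.14 ± 0.46 on the log2 scale (0.0111). The values of the others, which were not called, were 0.81 for Csf2, -0.76 for Cd40lg, 0.54 for Fos, 0.35 for Jun, 0.27 for Egr2, -0.20 for Nr4a1, -0.17 for Myc and 0.05 for Nfkbia. These 4 calls rest on few libraries, though the estimates moved less than the calls. By edgeR's quasi-likelihood test Ifng had adjusted p between 0.0609 and 0.207 without any 1 of the 5 stimulated libraries. Tnf had 0.0674, 0.0769 and 0.157 without the first Compound 10, first vehicle or second vehicle stimulated library. Il3 had 0.0965 and 0.0639 without the first or second stimulated vehicle library, while Cd69 had 0.0877 and Lipg 0.0911 without the first of these. In the fits that lost the call, the log2 fold change was 1.19 to 1.62 for Ifng, 0.81 to 1.08 for Tnf, -2.27 to -1.99 for Il3, 0.54 for Cd69 and -2.67 for Lipg.

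In all, 3350 genes differed in stimulated cells, 1502 higher and 1848 lower with the compound (44.8% higher), of which 922 and 1033 changed at least 2-fold. Scaling moved this split: with upper-quartile factors it was 2090 higher and 1528 lower, as the median gene then lay at 0.18. Without the first or the second stimulated vehicle library the count fell to 1630 and 1800. Sample index numbers kept with the libraries were grouped here into 3 runs (13 to 16, 19 to 22 and 25 to 29). The gap before 29, the third stimulated Compound 10 library, is as wide as those between runs. Placing that library in the third run was thus a choice. The first 2 runs held both stimulated groups. Within these the difference between compound and vehicle was of the same sign for Il2 (-3.55 and -2.91), Il2ra (-2.30 and -1.92), Nfatc1 (-1.62 and -1.35), Egr1 (2.89 and 2.21), Tnf (0.99 and 0.86), Btg2 (2.01 and 2.04) and Arl5c (4.35 and 4.14). Both runs had the sign of the call for 3348 of all 3350 called genes. The same libraries gave the calls, so this agreement was nearly fixed in advance and is no separate check.

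Among the lists, Myc targets and ribosome biogenesis genes fell in stimulated cells given the compound. Of 30, 21 were lower and 0 higher (23 lower adjusted over the list alone), with a median log2 fold change of -0.85 (camera adjusted p = 2.03e-12, and adjusted p = 0.0211 with an estimated correlation). Examples were Polr1b, a subunit of RNA polymerase I (-2.61 ± 0.24), and the nucleolar factors Noc3l (-2.16 ± 0.21), Nop2 (-1.71 ± 0.15) and Ppan (-1.55 ± 0.16). Of 24 activation surface and nutrient proteins 7 were lower and 2 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.00558, and adjusted p = 0.324 with an estimated correlation). Among them were the receptor genes Cd160 (-4.12 ± 0.35) and Tnfrsf9 (-1.77 ± 0.19), while Cd274, the gene of the inhibitory ligand PD-L1, rose (1.62 ± 0.20). Of 30 naive and quiescent genes 9 were higher and 2 lower (11 and 4 over the list alone; the same pair of adjusted p-values, 0.00558 and 0.324). The higher ones were led by the interleukin-7 receptor gene Il7r (2.36 ± 0.18) and Rasgrp2 (1.62 ± 0.19), with Il6st lower (-1.56 ± 0.28). Of 27 NF-kB targets 6 were higher and 2 lower (7 and 2 over the list alone; adjusted p = 0.0415, and adjusted p = 0.412 with an estimated correlation). Members included the adhesion gene Icam1 at 1.84 ± 0.20, Tnip1 at 1.60 ± 0.18, Birc3 at 1.15 ± 0.15 and Ripk2 at 1.02 ± 0.15.

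The remaining 12 lists did not pass camera, though single members changed. Of 24 cytokine genes 7 were lower and 3 higher (8 and 3 adjusted over the list alone; camera adjusted p = 0.106), including Tnfsf14 (-3.07 ± 0.43), Ltb (-1.52 ± 0.27) and Fasl (-1.24 ± 0.18). The rotation test fry, which asks whether a set moves on balance one way and compares it with no other genes, gave adjusted p = 0.00247 for this list. Of 30 immediate-early and MAPK feedback genes 8 were higher and 5 lower (10 and 6 over the list alone; 0.254), with the antiproliferative gene Btg2 at 2.02 ± 0.14, Klf6 at 1.57 ± 0.15 and the RNA decay factor gene Zfp36l1 at -1.23 ± 0.14. Of 18 AP-1 and related factors 2 were higher and 1 lower (1 and 0 over the list alone; 0.554), with Junb at 1.20 ± 0.17. NFAT and exhaustion genes had 3 higher and 5 lower of 26 (3 and 6 over the list alone; 0.513), the lower ones including Nr4a3 (-1.04 ± 0.19). Heat shock genes had 3 higher and 5 lower of 17 (3 and 5 over the list alone; 0.571), with the inducible chaperone gene Dnajb1 at 1.87 ± 0.31 and the mitochondrial chaperonin gene Hspd1 at -0.87 ± 0.15. Glycolysis and hypoxia genes had 3 higher and 9 lower of 27 (3 and 9; 0.401), with Pgam1 at -1.42 ± 0.13, Ldha at -0.95 ± 0.15 and Pdk1, which restrains pyruvate oxidation, at 1.45 ± 0.19. Cholesterol synthesis genes had 6 higher and 8 lower of 27 (7 and 8 over the list alone; 0.573), with Cyp51 at -1.56 ± 0.19. Stress and unfolded protein response genes had 5 and 4 of 25 (6 and 4; 0.554), and NRF2 targets 2 and 4 of 27 (2 and 4; 0.718) with the heme oxygenase gene Hmox1 3.997-fold lower. For p53 targets the counts were 5 and 3 of 23 (6 and 3; 0.329), for interferon response genes 4 and 0 of 26 (3 and 0; 0.121) with Stat2 at 1.75 ± 0.22, and for aryl hydrocarbon receptor targets 0 and 2 of 4 (0 and 2; 0.254). Of the cell type marker lists none passed camera in this comparison (adjusted p between 0.681 and 0.961), with 3 T cell identity genes lower and 0 higher of 10. In this comparison the median and the mean differed in sign for the heat shock, NFAT, stress response and T cell identity lists.

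**Figure D3:**
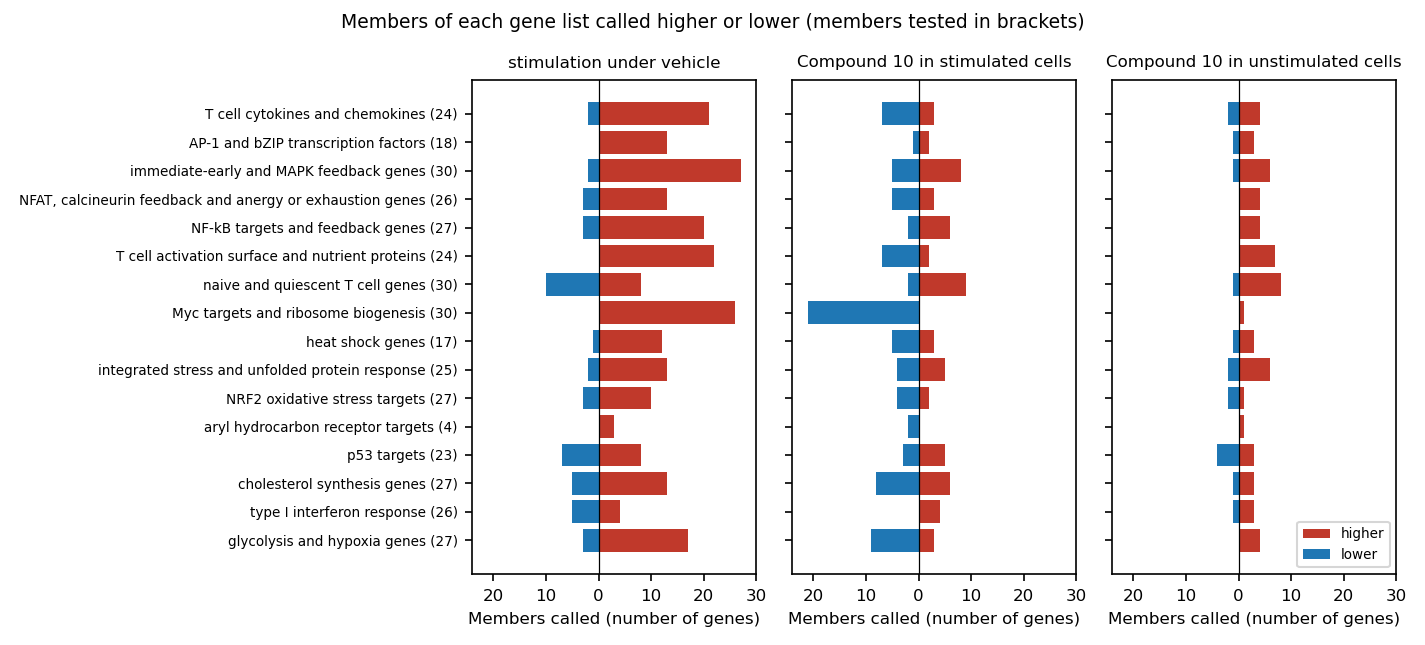
Number of members of each of the 16 gene lists called higher (bars to the right) or lower (bars to the left), with the members tested in brackets, for stimulation under vehicle and for Compound 10 in stimulated and in unstimulated cells. Of the 30 Myc and ribosome biogenesis genes 26 were higher with stimulation under vehicle and 21 were lower with Compound 10 in stimulated cells.

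How much of the stimulation response was altered was asked of the genes that changed at least 2-fold under vehicle. Of 1959 induced genes 580 were lower with Compound 10 in stimulated cells (29.6%, Wilson 95% interval 27.6% to 31.7%), 111 were higher, and 1188 were still called induced in cells given the compound. The median induction was 1.72 on the log2 scale under vehicle and 1.06 with the compound. Of 1860 repressed genes 495 were higher with the compound (26.6%, 24.7% to 28.7%), 56 were lower, and 889 were still called repressed, and the medians were -1.59 and -0.81. The stimulated vehicle libraries enter both sides of these shares. In 20 simulations with no compound effect the induced share reached at most 0% and the repressed share at most 0.0442%. Each simulation called at most 1 gene for the compound, so these shares cannot show how far the choice of genes raises the observed ones. Independent lists would give 12.8% and 10.4%. Across genes the correlation of the stimulation effect under vehicle with the compound effect was -0.423 (-0.270 on average in the simulations) and the covariance -0.661 (-0.275). With the genes chosen by the average of both stimulation effects the shares were 20.7% and 17.0%, and by the effect with the compound alone 15.5% and 7.49%, though these choices also leave out genes that the compound itself weakened. Without the first stimulated vehicle library the repressed share was 15.9%.

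Compound 10 also changed unstimulated cells. Tpx2 rose from 2.02 ± 0.993 CPM (SD, n = 3) to 22.3 ± 0.818 CPM (SD, n = 2), a log2 fold change of 3.50 ± 0.37, and other mitotic genes rose with it, the kinetochore motor gene Cenpe by 3.12 ± 0.22 and the checkpoint kinase gene Bub1b by 3.10 ± 0.34. The fatty acid elongase gene Elovl4 rose by 3.30 ± 0.44 and Sytl3 by 3.00 ± 0.32. Within the limits of abundance and overlap, the largest falls were those of Tspoap1 (36.8 ± 8.51 to 4.06 ± 0.147 CPM, -3.17 ± 0.24), the adenosine kinase gene Adk (-2.73 ± 0.18, from 199 ± 23.7 to 29.97 ± 2.997 CPM), the cytokine gene Lif (-2.56 ± 0.44), Tmem229b (-2.24 ± 0.51) and the stress-induced factor gene Atf3 (-2.23 ± 0.50). Lif passed the limit of abundance, an average over all libraries, through the stimulated libraries (16.3 to 44.6 CPM). In unstimulated cells it was near the floor, at 0.606 to 1.23 CPM with vehicle and 0.128 and 0.176 CPM with the compound. Of the panel only Egr2 was called, at -1.54 ± 0.31 (adjusted p = 0.0150, edgeR quasi-likelihood, Benjamini-Hochberg). Without the second Compound 10 library of this comparison the edgeR adjusted p was 0.121 for Egr2, 0.0757 for Lif, 0.0669 for Tmem229b and 0.157 for Atf3. Without the first vehicle library it was 0.0526 for Atf3 and 0.0527 for Tmem229b, which also stood at 0.0649 without the second. The log2 fold change in these fits was -1.31 for Egr2, -2.85 for Lif, -2.25 to -1.46 for Tmem229b and -1.66 to -1.53 for Atf3.

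In all, 1215 genes differed in unstimulated cells, 670 higher and 545 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted), and with no scaling 470 and 637. This count depended on the model and on single libraries. It was 2403 with the index runs as a block, 1900 by DESeq2 and 1828 by limma-voom. It was 351 without the second unstimulated Compound 10 library, 681 without the first, and 567 and 608 without the first or second unstimulated vehicle library. It was 798 and 808 without the first or second stimulated vehicle library, which enters through the shared spread, and 123 when the 2 groups were fitted alone. The 6 lists that rose by camera were lost with an estimated correlation (adjusted p = 0.423 for NF-kB targets and 0.300 for the others). Activation surface proteins had 7 of 24 higher and 0 lower (10 adjusted over the list alone; camera adjusted p = 0.00131), with the T cell inhibitory receptor gene Cd5 at 1.80 ± 0.21, Il2rb at 1.76 ± 0.29 and Cd44 at 1.42 ± 0.25. Immediate-early and MAPK feedback genes had 6 of 30 higher and 1 lower (8 and 1 over the list alone; 0.00131), with the phosphatase genes Dusp6 and Dusp5 at 1.22 ± 0.18 and 1.17 ± 0.17 and Klf6 at 0.89 ± 0.14. Naive and quiescent genes had 8 of 30 higher and 1 lower (14 and 2; 0.00488), with Il7r at 2.08 ± 0.16 and Pik3ip1 at 1.32 ± 0.17. The stress and unfolded protein response had 6 and 2 of 25 (10 and 2; 0.0371), and NF-kB targets 4 and 0 of 27 (4 and 0; 0.0399) with Cflar, an inhibitor of caspase activation, at 0.90 ± 0.14. Glycolysis and hypoxia genes had 4 and 0 of 27 (5 and 0; 0.0399) with the hexokinase gene Hk2 at 2.13 ± 0.30.

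Among the lists that did not pass camera in unstimulated cells (adjusted p between 0.144 and 0.940), cytokine genes had 4 higher and 2 lower of 24 (5 and 3 adjusted over the list alone), with Tnfsf11 at 2.08 ± 0.21 and Tnfsf8 at 1.60 ± 0.25. Heat shock genes had 3 and 1 of 17 (4 and 1), with Hspa1a, an inducible chaperone, at 2.12 ± 0.22. AP-1 and related factors had 3 and 1 of 18 (5 and 2) with Nfil3 at 1.35 ± 0.22, NFAT and exhaustion genes 4 and 0 of 26 (4 and 0), and p53 targets 3 and 4 of 23 (5 and 6) with the cell cycle inhibitor gene Cdkn1a at 1.86 ± 0.22. Interferon genes had 3 and 1 of 26 (5 and 2), cholesterol synthesis genes 3 and 1 of 27 (3 and 1), NRF2 targets 1 and 2 of 27 (2 and 2), and aryl hydrocarbon receptor targets 1 and 0 of 4 (2 and 0). Myc targets and ribosome biogenesis genes had 1 of 30 higher and 0 lower (0 and 0 over the list alone). Of 10 T cell identity markers 1 was higher and 0 lower (Cd28 at 1.25 ± 0.22; camera adjusted p = 0.0176, and adjusted p = 0.245 with an estimated correlation).

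The compound's effects in stimulated and in unstimulated cells, which share no library, correlated across the 14417 genes with Pearson r = 0.266 and Spearman rho = 0.332, and r = 0.440 over the 8033 genes with an average log2 CPM of at least 3. With the replicate number as a block r was 0.155. Both effects were called for 624 genes, the mitotic genes Tpx2 and Cenpe and the receptor gene Il7r among them. Of these, 323 were higher in both and 241 lower in both, against 69.8 and 69.9 for independent lists. Another 23 were higher in stimulated and lower in unstimulated cells and 37 the reverse, against 56.8 and 85.9. Of the 3941 genes called in either state 75.5% had the same sign, against 62.5% of all 14417 genes tested.

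Whether stimulation acted differently with the compound was tested as the interaction. The stimulation effect was lower with the compound for Sema7a, Nckap1, the inhibitory receptor gene Btla, Net1 and the Hedgehog receptor gene Ptch1. The differences were -3.67 ± 0.44, -3.40 ± 0.49, -3.39 ± 0.41, -3.39 ± 0.21 and -3.30 ± 0.50 on the log2 scale. Those of Il2ra (-2.03 ± 0.33) and Nfatc1 (-1.33 ± 0.27) had the same sign. Differences in the other direction were those of Arl5c (3.19 ± 0.24), Tspoap1 (3.11 ± 0.31), Rundc3b (2.78 ± 0.59), Sh3d21 (2.69 ± 0.58), Txnl4b (2.65 ± 0.46), Egr1 (2.24 ± 0.27) and Egr2 (1.81). Some came largely from unstimulated cells. There Net1 stood at 36.7 to 47.0 CPM with vehicle and 289 to 300 CPM with the compound, against 158 to 168 and 99.4 to 113 CPM in stimulated cells. Tspoap1 fell in unstimulated cells and stood at 49.2 to 57.2 and 46.8 to 54.8 CPM in stimulated cells. Egr2 was called only in unstimulated cells. Nckap1, in contrast, differed mainly in stimulated cells. The estimate for Il2 was -2.61 ± 1.38 and was not called, since its unstimulated groups held 4 and 2 counts. Without the first stimulated vehicle library the adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg) was 0.0862 for Nfatc1, 0.0711 for Rundc3b, 0.0580 for Txnl4b and 0.131 for Egr2. Without the second of these libraries it was 0.0618 for Nfatc1, 0.101 for Sh3d21 and 0.1003 for Egr2. Without the second unstimulated Compound 10 library it was 0.0568 for Rundc3b and 0.107 for Egr2, and 0.0501 for Nfatc1 without the first of that group. Without the second unstimulated vehicle library it was 0.0508 for Sh3d21 and 0.0540 for Egr2, and it lay between 0.0528 and 0.0663 for Egr2 without any 1 stimulated Compound 10 library. The differences in these fits were -1.38 to -1.02 for Nfatc1, 2.21 to 2.77 for Rundc3b, 2.20 to 2.54 for Sh3d21, 2.52 for Txnl4b and 1.57 to 1.87 for Egr2. The call for Il2ra ended with offsets for transcript length.

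In all, 956 genes responded to stimulation differently with the compound, 368 with a higher and 588 with a lower stimulation effect (38.5% higher). Of the 588, 479 were induced under vehicle, 13 repressed and 96 not called, and of the 368, 306 were repressed, 8 induced and 54 not called. The split was 494 and 476 with upper-quartile factors and 527 and 314 with no scaling, where the median gene lay at 0.18. The count was 2167 with the index runs as a block, 1735 without the third index run, 1692 by DESeq2, 1448 with no filter and 636 with length offsets. It was 198 and 311 without the first or second stimulated vehicle library and 466 without the second unstimulated Compound 10 library. It was 527 without the second unstimulated vehicle library, and 513 and 571 without the first or second stimulated Compound 10 library. Myc targets and ribosome biogenesis genes had 15 of 30 lower and 0 higher (18 adjusted over the list alone; camera adjusted p = 1.69e-13, and adjusted p = 0.0156 with an estimated correlation), with Polr1b at -2.67 ± 0.33, Noc3l at -2.09 ± 0.30 and Gnl3 at -1.27 ± 0.17. Activation surface proteins had 10 of 24 lower and 0 higher (10 and 1 over the list alone; 2.18e-07, and adjusted p = 0.0648 with an estimated correlation), with Cd160 at -3.95 ± 0.50, Il2rb at -3.18 ± 0.41 and Tnfrsf9 at -2.64 ± 0.28. Glycolysis genes had 3 of 27 lower and 0 higher (8 and 1; 0.0112, and adjusted p = 0.289 with an estimated correlation), with Pgam1 at -1.34 ± 0.19. Aryl hydrocarbon receptor targets had 2 of 4 lower and 0 higher (2 and 0; 0.0216, and adjusted p = 0.161 with an estimated correlation), with Tiparp at -1.29 ± 0.21. The other 12 lists did not pass (adjusted p between 0.0527 and 0.771), with 5 of 24 cytokine genes lower and 2 higher (5 and 3), among the lower ones Tnfsf14, with 3 counts in all unstimulated vehicle libraries. Of 10 T cell identity markers 2 had a lower and 0 a higher stimulation effect with the compound (camera adjusted p = 0.0339, and adjusted p = 0.309 with an estimated correlation).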

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

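The interaction test, the scalings by RLE and the choice of induced genes were planned, while upper-quartile scaling, no scaling and the tests of a uniform weakening were chosen after the result was seen. Stimulation acted differently in cells given Compound 10 and in cells given vehicle for 956 genes by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment. Among the named genes the stimulation effect with Compound 10 minus that with vehicle, on the log2 scale, was 3.19 for Arl5c, 3.11 for Tspoap1, 2.78 for Rundc3b, 2.69 for Sh3d21, 2.65 for Txnl4b, 2.24 for Egr1 and 1.81 for Egr2. It was -3.67 for Sema7a, -3.40 for Nckap1, -3.39 for both Btla and Net1, -3.30 for Ptch1, -2.03 for Il2ra and -1.33 for Nfatc1. For Net1, Tspoap1 and Egr2 the difference came largely from unstimulated cells, as described above. The count rose to 2167 with the index runs as a block, 1735 without the third index run and 1692 by DESeq2. It fell to 198 without the first and 311 without the second stimulated vehicle library, to 466 without the second unstimulated Compound 10 library, to 527 without the second unstimulated vehicle library, and to 513 and 571 without the first or second stimulated Compound 10 library.

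In stimulated cells many induced genes were lower with Compound 10 while the immediate-early genes Egr1, Btg2 and Junb were higher, as was Klf6, which stimulation lowered under vehicle (-1.96), and Junb and Klf6 were higher in unstimulated cells too (0.92 and 0.89, though Junb was no longer called, at 0.77, in 1 of the fits that left out a library). The scaling of the libraries was tested as an explanation: under RLE, upper-quartile and no scaling 100%, 86.7% and 87.2% of the induced genes called lower were still called, and all 4 of these genes were still called higher (Egr1 between 2.53 and 2.69), so scaling alone cannot account for the pattern. Choosing induced genes on the vehicle libraries they are compared with is argued against as the whole cause by the choice on the average stimulation effect. Of those genes 20.66% were still lower, against 12.8% for independent lists. Of genes induced with the compound, a choice that works against finding lower genes, 15.5% were lower, little above 12.8%. For repressed genes the share higher was 17.0% by the average effect and 7.49% by the effect with the compound, against 10.4% for independent lists. The value of 7.49% thus lay below its reference. How much of the 29.6% comes from choosing on the vehicle libraries stays open, since the other choices also leave out genes that the compound weakened. A uniform weakening of the response, as a lower dose of stimulus would give, was also examined. Among genes induced under vehicle the stimulation effect was called lower with the compound for 479 and higher for 8. Choosing these genes on vehicle libraries that also enter the interaction favours lower effects, and a selective weakening could give this split too. Egr1, Btg2 and Egr2 were among the 8 (2.24, 2.07 and 1.81). Egr2 was called lower with the compound in unstimulated cells and was not called in stimulated cells, so its difference came largely from the former. In stimulated cells 111 induced genes were higher, a count that also holds effects present without stimulation. Medians of lists fixed in advance argue against a single common factor for their genes. From vehicle to compound the median stimulation effect went from 1.47 to 0.38 for Myc targets, 1.60 to 1.69 for NF-kB targets and 2.89 to 2.57 for immediate-early genes. For most other genes a uniform weakening stays open.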

How the results depend on the processing

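Leaving out the third index run, upper-quartile scaling and no scaling were chosen after seeing the data, and the other alternatives were planned. Across 425 values of named genes, leaving out 1 library kept the direction and the side of the threshold in 3842 of 4250 cases, lost a call in 402 and gained 6, with none reversed. The other settings kept 5206 of 5428, lost 192, gained 27 and reversed 3: with no scaling Nfe2l2 and Capg stood at -0.17 and -0.24 in the stimulation effect under vehicle (0.61 and 0.53 with TMM), and G6pdx at -0.0022 in that with Compound 10 (0.59), as the whole distribution shifts without scaling factors. For the changes that follow the cause was not tested, except that a stricter threshold leaves fewer calls by construction. Counts that stayed within 1.5 times and shares that stayed within their interval are not listed. Depth limits the unstimulated levels of Il2, Il3, Csf2 and Ifng, which rest on at most 6 counts per group.

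Leaving out each library gave 3606 to 5759 genes for stimulation under vehicle, 2398 to 4347 for stimulation with Compound 10, 1630 to 3900 for Compound 10 in stimulated cells, 351 to 1313 in unstimulated cells and 198 to 1323 for the interaction. The induced share ranged from 21.7% to 33.3% and the repressed share from 15.9% to 32.4%. The lists called ranged from 11 to 13 for stimulation under vehicle, 3 to 5 and 4 to 6 for Compound 10 in stimulated and unstimulated cells, and 3 to 6 for the interaction, and the correlation of the compound effects from 0.193 to 0.269. The lowest counts came without the first stimulated vehicle library or the second unstimulated Compound 10 library. A library left alone in its group is then assumed to vary like the other groups.

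At an adjusted p under 0.01 the counts were 2133 for stimulation with Compound 10, 1851 and 284 for Compound 10 in stimulated and unstimulated cells, and 238 for the interaction. With an absolute log2 fold change of at least 1 they were 2273, 1955 and 636 for the first 3 of these. DESeq2 gave 1900 genes in unstimulated cells, 1692 in the interaction and an induced share of 33.1%, and limma-voom gave 1828 in unstimulated cells and a repressed share of 17.7%. Fitting only the groups compared gave 123 in unstimulated cells. In the interaction no filter gave 1448 and length offsets 636, with an induced share of 27.3%, and the stricter filter gave shares of 36.2% and 32.1%. Without the third index run the interaction had 1735 genes and the shares were 37.0% and 34.2%. With no scaling 6029 genes were called for stimulation with Compound 10 and the repressed share was 23.1%, and with upper-quartile scaling the shares were 25.7% and 34.4%. Chosen by the average stimulation effect the shares were 20.7% and 17.0%, by the effect with Compound 10 15.5% and 7.49%, and with a log2 effect of at least 2 the repressed share was 28.9%. With an estimated correlation 6 lists were called for stimulation under vehicle, 1 and 0 for Compound 10 in stimulated and unstimulated cells and 1 for the interaction, and fry called 10 in stimulated cells. Over genes with an average log2 CPM of at least 3 the compound effects correlated with r = 0.440.

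Whether the label numbers pair the libraries cannot be told here. Deviations from the group means of same-numbered libraries correlated above 0.1 in 9 of 13 pairs (mean 0.147, minimum -0.494), against 8 of 24 pairs with different numbers. In a group of 2 libraries the deviations mirror each other, so many of these signs are fixed together. With the replicate number as a block the interaction had 1504 genes, the shares were 33.2% and 31.2% and the compound effects correlated with r = 0.155. For libraries of the same index run 9 of 12 pairs were above 0.1 (mean 0.229, minimum -0.204), against 8 of 25 pairs of different runs. With the index run as a block 2403 genes were called in unstimulated cells, 1210 of the 1215 among them, and 2167 in the interaction, with all 956 among them, and the shares were 35.6% and 35.1%.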

Other observations

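The protein families, the individual genes named in this part and the test of depth on the third index run were chosen after the values were seen, while the other tests were written before their results. Subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, were lower with Compound 10. In stimulated cells 23 of 38 were lower and 1 was higher, with a median log2 fold change of -0.74 (Fisher's exact test against the other genes, adjusted p = 1.96e-10 over 11 families in 3 comparisons), and in unstimulated cells 9 were lower and 1 higher (adjusted p = 4.96e-05). Examples in stimulated cells were Psma5 (-1.73), Psmc2 (-1.69) and Psmd2 (-1.16), while the exception was Psmb9, a subunit of the immunoproteasome (1.37). Under the other 3 scalings between 20 and 23 were lower in stimulated and between 8 and 11 in unstimulated cells. Of the other 10 families, 4 were more often lower in stimulated cells than other genes: 17 of 39 initiation factors (1 higher; adjusted p = 1.30e-05), 23 of 50 DEAD and DEAH box helicases (3 higher; 1.46e-07; 22 lower and 6 higher under upper-quartile scaling), 14 of 37 genes of tRNA charging (4 higher; 0.000496; 12 lower and 6 higher under upper-quartile scaling) and 4 of 6 chaperonin subunits (0 higher; 0.0119; 2 lower under upper-quartile scaling). With the index runs as a block 25 helicases were lower and 9 higher. The tRNA charging genes had a median of -0.16, and the 4 higher ones were Fars2, Iars2, Mars2 and Sars2, while Yars2 was lower (-1.85). The tRNA synthetase genes Tars and Cars stood at -2.38 and -2.36. Ribosomal protein genes were called less often than other genes in both directions (1 of 80 lower, 0 higher; Fisher adjusted p = 0.00137 for lower and 0.00198 for higher). Nucleoporins (5 of 20 lower; 0.318) and karyopherins (6 of 22 lower; 0.128) did not pass. Genes are not independent, and Fisher's test treats them as such.

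Some genes of mitosis were higher with Compound 10 in both states. Of 49 tested genes of a mitosis list written after Tpx2 and Cenpe had been seen to lead, 19 were higher and 1 lower in stimulated cells (median 0.88) and 16 and 1 in unstimulated cells (median 0.59), and 14 were higher in both. These 14 were Tpx2, Cenpe, Plk4, Incenp, Anln, Ttk, Bub1b, Ndc80, Nusap1, Kif23, Top2a, Cenpa, Prc1 and Ccnb1, with Anln, a cytokinesis scaffold, at 3.91 in stimulated and 4.17 in unstimulated cells and the centriole kinase gene Plk4 at 3.03 and 2.90. The proliferation markers Mki67, Ccna2, Cdk1, Birc5, Hmmr, Plk1, Aspm and Cenpf, 8 genes picked after their values were seen, reached at most 6.26 CPM in any Compound 10 library. In any vehicle library they reached at most 6.88 CPM. The highest level was in a vehicle library for Hmmr, Plk1, Aspm and Cenpf and in a Compound 10 library for Mki67, Ccna2, Cdk1 and Birc5. Incenp stood at 81.5 CPM or more in all Compound 10 libraries. All these levels were scaled to library totals without TMM factors.

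Dividing cells in the Compound 10 libraries were tested as an explanation of the higher mitotic genes. Of 50 tested DNA replication genes 10 were higher and 8 lower in stimulated cells and 7 and 6 in unstimulated cells. Their medians were 0.208 and -0.0244, below the mitotic medians by more than the sum of the standard errors of both lists. These errors were 0.19 (mitosis) and 0.13 (replication) in stimulated cells and 0.17 and 0.096 in unstimulated cells. They are errors of the mean over genes, which are not independent. The gaps also lay within the margin set beforehand for dividing cells, so both predictions were met and the test cannot decide. Replication genes also have a high baseline here (median average log2 CPM 4.68 against 1.88), which weakens this test further. Reads from annotated non-coding transcripts are argued against for only some of the 14 mitotic genes higher in both states. A median of 99.3% of the counts of the 14 in Compound 10 libraries lay on protein-coding transcripts (98.2% in vehicle libraries). A gene with no annotated non-coding transcript scores 100% whatever its reads are. Ndc80, Incenp, Plk4, Kif23 and Anln, at 100%, may be such genes and decide nothing. For Top2a, Prc1, Tpx2, Bub1b, Nusap1 and Cenpe the share lay between 87.0% and 99.9%. The share was 11.6% for Cenpa and 66.3% for Ccnb1, and for Ttk 85.6% against 0.0015% with vehicle. It cannot tell whole from partial coding transcripts, so partial ones stay open. The index run is argued against too, since 100% of these 14 genes stayed higher in both states with the runs blocked. Nearly all genes called in unstimulated cells also stayed called then, so this is not particular to mitotic genes. A block by run does not test depth, which stays open. A candidate explanation is that the compound raises transcripts of part of the mitotic genes without division, a hypothesis found on these data, and protein levels and cell counts were not analysed here.

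The libraries placed in the third index run (the third unstimulated vehicle, the second unstimulated Compound 10 and the third stimulated Compound 10 libraries) deviated together from their group means. A greater depth of the run was tested by thinning all libraries to 10630000 counts, after which the deviations of the third stimulated Compound 10 library, of ordinary depth, still correlated across genes with those of the deep pair (0.400 and 0.255), which argues against depth as the whole cause. Across 7800 genes the deviations correlated with log transcript length in all 3 libraries (Spearman rho -0.361, -0.224 and -0.423) and with GC content in mixed directions (-0.0998, -0.223 and 0.250). This is consistent with a difference in library preparation that acts by transcript length, and no biological explanation was tested, since the run is not a group of the design.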
